A study of Homo sapiens with 33 samples.

How the data were processed

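Gene expression was measured by 3' tag sequencing of poly(A) RNA (QuantSeq 3' mRNA FWD, in which each transcript gives reads next to its 3' end) in 33 libraries of the breast cancer cell lines that the labels spell MDA-MD-231 and MDA-MD-468. The inhibitor part holds 22 libraries: in each of the 2 lines, a DMSO and an untreated (parental) library at 0 h, and SY200, V50 and the combination SY200/V50 at 3, 6 and 12 h. The knockout part holds 11 MDA-MD-231 libraries: a parental library, and empty vector, CDK1 KO, CDK7 KO, CDK9 KO and CDK7/9 KO at 72 and 96 h. The series describes the treatments as CDK7 inhibitor, CDK9 inhibitor and both. The labels do not say which of SY200 and V50 acts on which kinase, nor the unit of the numbers in these names, so the labels' names are used throughout. Within each part, each combination of line, condition and time has 1 library. P-values thus rest mainly on how effects differ between lines (inhibitors) or times (knockouts), not on repeats. Separate cultures are not stated.

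The deposited values are whole-number read counts per gene symbol, 1 column per library, not normalized. Reads were aligned with STAR 2.7.10a to GRCh38 and checked with FastQC, per the submitters' processing notes. The counting tool, annotation release, strand setting, trimming and any use of molecular identifiers are not given in the sources used here. Reads without molecular identifiers are not independent molecules. The table has 59428 entries, 698 of them named only by an Ensembl ID. Each library's counts summed to between 16985219 and 22859779. DMSO and parental libraries of a line were fitted as repeats in the treatment tests, but differed by more than sampling noise. Chi-square per degree of freedom was 44.5 in MDA-MD-231 and 27.5 in MDA-MD-468. Gene positions were taken from GENCODE release 29 on GRCh38.

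Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the design, with a minimum count of 10 and a minimum total of 15, which left 18911 genes in the inhibitor part and 16783 in the knockout part. Libraries were scaled by TMM factors and tested with the quasi-likelihood F test, and Benjamini-Hochberg (BH) adjusted p under 0.05 was the threshold, with no threshold on the fold change. The inhibitor model had the cell line as a block and a condition with 10 levels: control, made of the 4 DMSO and parental libraries, and each treatment at each time (11 residual degrees of freedom). From it came each treatment against control at each time and as the mean of the times, the combination against each single agent, the combination against the sum of the single effects, and 12 h against 3 h. A model with a term for each treatment in MDA-MD-468 compared the lines (8 residual degrees of freedom), and a model with DMSO and parental apart compared these (10). The knockout model had time and genotype over the 10 libraries with an empty vector or a knockout (4 residual degrees of freedom). The parental library of that part was left out because it has no matching time. A gene's log2 fold change is given ± the standard error implied by its F statistic, and CPM means counts relative to the TMM-scaled library size.

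These comparisons, the lists, the rule for the genes to be named and the alternatives were fixed before the data were examined. Gene lists were tested with camera (limma 3.58.1, 2-sided, preset inter-gene correlation of 0.01), BH-adjusted over the 22 lists within a comparison. The lists held immediate-early, anti-apoptotic, pro-apoptotic, p53 target, homologous recombination and Fanconi, DNA replication and E2F, G2 and mitosis, transcription elongation and P-TEFb, histone, cytosolic ribosomal protein, mitochondrially encoded mRNA, nuclear oxidative phosphorylation, integrated stress response, heat shock, NF-kB and inflammatory, interferon-stimulated, cholesterol synthesis, oncogenic transcription factor and receptor, YAP and TEAD target, zinc finger, snoRNA host and nuclear noncoding RNA, and hypoxia and glycolysis genes. Another 3 lists held markers of each line and of immune cells. The genes named are CDK1, CDK7 and CDK9, then in each comparison up to 8 with the largest rise and 8 with the largest fall among genes past the threshold with a mean of at least 10 CPM and the same sign in both lines or at both knockout times, and up to 4 members of each described list with the smallest adjusted p. Members of lists may also be named where they did not pass. Values of named genes at single times, of genes in comparisons with few calls, and of genes other than these are stated to be chosen after the values were seen. Some genes that the rule would name are not reported here.

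The alternatives were DESeq2's median-of-ratios size factors within the edgeR fit, no filter on low counts, DESeq2 1.42.0 with the same designs, scaling each library to its 13 mitochondrially encoded mRNAs, DMSO alone as the control, no block for the line, no block for the time, and leaving out each library in turn. Mitochondrial mRNAs are made by another polymerase than RNA polymerase II, so this scaling asks what the values would be if their amount per cell had stayed constant, which was not measured. Camera was repeated with an estimated correlation, the correlation of inhibitor and knockout effects with genes of at least 10 CPM in both parts, and the targets' levels with CPM from total counts.

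The steps were tested on simulated counts drawn from the real means and library sizes, with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold. In the simulation of the combination against control (17722 genes) 17.9%, 65.7% and 93.9% of these were recovered, and 9.92% of the calls were of unchanged genes. For the combination against V50 the shares recovered were 28.4%, 77.6% and 98.5%, with 13.4% of calls of unchanged genes. For the difference of the combination's effect between the lines they were 0%, 4.48% and 48.5%, with 2.78%. For CDK7 KO (16190 genes) they were 37.3%, 92.5% and 97%, with 5.62%. It was 12.6% for SY200, 12.1% for the departure from the sum, 12.5% for V50 at 12 h against 3 h, 9.09% for V50 at 3 h, 13% for DMSO against parental and 19.7% for SY200/V50 against V50 at 3 h. The share of false calls was thus above the nominal 5% in each simulated comparison except the difference between the lines. Of 100 random lists tested with camera in each part, 2 and 0 had p under 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.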

Results

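The series asked what blocking the transcriptional kinases CDK7 and CDK9, alone or together, does to gene expression over time. CDK7 is part of the general transcription factor TFIIH and activates other cyclin-dependent kinases. CDK9 is the kinase of P-TEFb, which releases paused RNA polymerase II. Cells of the triple-negative breast cancer lines labelled MDA-MD-231 and MDA-MD-468 were treated with SY200, V50 or both for 3, 6 and 12 h (18 libraries), with 4 DMSO and parental libraries as controls. Cells of MDA-MD-231 with an empty vector or with CDK1, CDK7, CDK9 or both CDK7 and CDK9 knocked out were measured at 72 and 96 h (10 libraries), with 1 further parental library. The 3' tag libraries held 16985219 to 22859779 counted reads each. Fold changes are on the log2 scale and named genes had the same sign in both lines, or at both knockout times, where they are introduced as largest rises or falls.

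The libraries carried the marker genes of the line they are labelled with. The 14 MDA-MB-231 identity markers had a median of 186 to 352 CPM in the MDA-MD-231 libraries and 3.17 to 8.77 CPM in those of MDA-MD-468. The 19 MDA-MB-468 identity markers had a median of 138 to 213 CPM in MDA-MD-468 and 0.484 to 2.98 CPM in MDA-MD-231. The 10 immune cell markers summed to 2.21 to 22.7 CPM. In the inhibitor part the 13 mitochondrially encoded mRNAs, which RNA polymerase II does not make, took a larger share of the counts at 12 h of each treatment than with DMSO. In MDA-MD-231 they made up 2.51% with DMSO, 2.65% with SY200 at 12 h, 3.82% with V50 at 12 h and 5.05% with SY200/V50 at 12 h. In MDA-MD-468 the shares were 3.93%, 5.72%, 7.42% and 13.5%. The share rose at each time with SY200/V50 in both lines, but not with SY200 (in MDA-MD-468 6.67%, 5.66% and 5.72% at 3, 6 and 12 h) or with V50 in MDA-MD-468 (7.38%, 7.75% and 7.42%). TMM scaling sets the bulk of genes to no change, so each rise and fall below is relative to that bulk. Scaling to the mitochondrial mRNAs instead brought the median log2 change of all genes from -0.01 to -0.44 for SY200, from -0.004 to -0.92 for V50 and from 0.09 to -1.33 for SY200/V50.

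SY200 lowered some mRNAs of G2 and mitosis and of snoRNA host genes, as lists only with the preset correlation, and raised POLR2A, which encodes the largest subunit of RNA polymerase II. POLR2A rose 2.69-fold as the mean of the times (1.43 ± 0.19, edgeR BH-adjusted p = 0.00196). ANKRD1, a target of YAP and TEAD, fell by 1.49 ± 0.13 (edgeR BH-adjusted p = 1.89e-05). The stem cell and lineage transcription factor SOX9 fell by 1.57 ± 0.23 (edgeR BH-adjusted p = 0.00404) and RABGGTB, a subunit of a Rab prenylation enzyme, fell by 1.17 ± 0.15 (edgeR BH-adjusted p = 0.00169). The largest fall was that of the WNT antagonist DKK1 (-2.09 ± 0.31, edgeR BH-adjusted p = 0.00404), a gene that also differed between the DMSO and parental libraries. BMP4 fell by 1.51 ± 0.37 (edgeR BH-adjusted p = 0.0445) and the chaperone gene HSPA8 fell by 1.21 ± 0.24 (edgeR BH-adjusted p = 0.0182). CYP4Z1, SLFN5, the protease gene CTSK and the decoy receptor gene TNFRSF10D had the other large rises, of 2.00, 1.54, 1.43 and 1.35, and the rise of CYP4Z1 was 0.18 in MDA-MD-231 and 2.06 in MDA-MD-468. Leaving out any 1 library ended no call for POLR2A, ANKRD1, SOX9, RABGGTB or DKK1. HSPA8 lost its call without the MDA-MD-231 SY200 6 h (-1.23), MDA-MD-468 SY200 3 h (-1.19), MDA-MD-468 DMSO (-1.12) or MDA-MD-468 parental library (-0.99). CYP4Z1, CTSK, TNFRSF10D, SLFN5 and BMP4 lost theirs without any of 5, 8, 8, 10 and 12 libraries. CDK1, CDK7 and CDK9 themselves did not pass the test with SY200 (-0.28 ± 0.14, -0.61 ± 0.20 and 0.02 ± 0.21), although CDK7 did without either SY200/V50 12 h library (-0.62 and -0.61).

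Of 28 genes of G2 and mitosis, 0 were higher and 8 lower with SY200, and 14 were lower when adjusted over the list alone (camera adjusted p = 3.85e-12, adjusted p = 0.0564 with an estimated correlation). Among them CCNB1, which encodes cyclin B1, fell by 0.54 ± 0.09 and the mitotic kinase gene AURKA fell by 0.68 ± 0.13. The ribonucleotide reductase gene RRM2 fell by 0.83 ± 0.17. AURKA lost its call without the MDA-MD-231 SY200 6 h (-0.69) or MDA-MD-468 SY200 3 h library (-0.63), and RRM2 and SNHG3 without any of 6 libraries. Of 21 snoRNA host and nuclear noncoding RNAs, 4 were lower over all genes and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00247, adjusted p = 0.503 with an estimated correlation), and SNHG3 fell by 1.15 ± 0.23. Histone genes went the other way, with 2 of 32 higher and 0 lower over all genes, and 12 higher adjusted over the list alone (camera adjusted p = 9.38e-09, adjusted p = 0.155 with an estimated correlation). H2BC12 rose by 0.82 ± 0.13, although reads of near-identical histone copies cannot be told apart with certainty. Mitochondrially encoded mRNAs had 8 of 13 members higher, and 11 adjusted over the list alone (camera adjusted p = 3.85e-12, adjusted p = 0.142 with an estimated correlation). In all, 375 genes passed the edgeR test, 183 higher and 192 lower, and under scaling to mitochondrial mRNAs 202 were higher and 5097 lower. The count was 44 with DMSO alone as the control, where POLR2A, ANKRD1 and RABGGTB stayed past the threshold and DKK1 (-1.03), SOX9 (-1.23) and the named cell cycle, snoRNA host and histone genes did not. Leaving out 1 MDA-MD-231 library gave 69 (SY200 6 h), 103 (SY200 3 h), 162 (parental), 219 (SY200 12 h), 245 (SY200/V50 6 h) and 624 (SY200/V50 12 h). The values for MDA-MD-468 were 59 (SY200 3 h), 72 (parental), 134 (SY200 12 h), 148 (DMSO), 243 (SY200/V50 6 h) and 607 (SY200/V50 12 h).

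V50 lowered the P-TEFb regulators HEXIM1 and MEPCE and p53 targets, and raised the relative level of mitochondrial mRNAs and, only with the preset correlation and TMM scaling, of mRNAs for ribosomal proteins. The P-TEFb inhibitor gene HEXIM1 fell 5.55-fold averaged over lines and times (-2.47 ± 0.16, edgeR BH-adjusted p = 3.22e-07). In MDA-MD-231 it had 169 (DMSO), 161 (parental) and 13.7 CPM (12 h). MEPCE, whose product caps the 7SK RNA that holds P-TEFb inactive, fell by 1.74 ± 0.17 (edgeR BH-adjusted p = 1.45e-05). Among the largest falls were DKK1 (-3.08 ± 0.32), the transcription factor FOXQ1 (-2.70 ± 0.35), BMP4 (-2.54 ± 0.38) and the phosphatase DUSP5 (-2.34 ± 0.30), with edgeR BH-adjusted p of at most 0.000429. The long noncoding RNA LINC00641 rose by 2.49 ± 0.34 (edgeR BH-adjusted p = 0.000202). FOS rose by 1.54 ± 0.51 (edgeR BH-adjusted p = 0.0393), a call lost with DMSO alone as the control and without any of 9 libraries. CDK7 fell by 0.73 ± 0.20 (edgeR BH-adjusted p = 0.0185), lost without the MDA-MD-231 DMSO (-0.66) or the MDA-MD-468 V50 3 h library (-0.68), while CDK1 (-0.06 ± 0.14) and CDK9 (-0.13 ± 0.21) did not pass.

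Of 24 p53 targets, 0 were higher and 9 lower with V50, and 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.000125, adjusted p = 0.0362 with an estimated correlation). The kinase genes PLK3 (-1.57 ± 0.19) and PLK2 (-1.67 ± 0.22) and the antiproliferative gene BTG2 (-2.01 ± 0.38) were among them. Pro-apoptotic genes had 8 of 20 members lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0204, adjusted p = 0.11 with an estimated correlation), with APAF1 at -1.02 ± 0.20 and FAS at -1.09 ± 0.24. Of 31 elongation and P-TEFb genes, 1 was higher and 8 lower, and 2 higher and 11 lower adjusted over the list alone (camera adjusted p = 0.0412, adjusted p = 0.295 with an estimated correlation). Zinc finger genes, a large class of transcription factors, had 9 of 495 members higher and 145 lower, and 11 and 156 adjusted over the list alone (camera adjusted p = 4.38e-11, adjusted p = 0.332 with an estimated correlation). Of 78 cytosolic ribosomal protein genes 73 were higher and 0 lower, and 76 higher adjusted over the list alone (camera adjusted p = 1.75e-30, adjusted p = 0.295 with an estimated correlation), but their median of 0.53 became -0.39 under mitochondrial scaling. Nuclear oxidative phosphorylation genes (30 of 49 higher, 36 adjusted over the list alone, camera adjusted p = 1.49e-15, adjusted p = 0.295 with an estimated correlation) turned in the same way, from 0.41 to -0.51. DNA replication and E2F genes had 8 of 36 members higher and 1 lower, and 12 and 2 adjusted over the list alone (camera adjusted p = 0.00517, adjusted p = 0.626 with an estimated correlation), with a median of 0.31 that became -0.62 under that scaling. FOXM1, an activator of mitotic genes, rose by 0.64 ± 0.09 on the TMM scale and was at -0.27 on the mitochondrial scale. All 13 mitochondrial mRNAs were higher, over all genes and adjusted over the list alone (camera adjusted p = 2.87e-19, adjusted p = 0.0362 with an estimated correlation). With V50 4225 genes passed the edgeR test, 1972 higher and 2253 lower, against 309 higher and 13964 lower under mitochondrial scaling. Leaving out the MDA-MD-468 V50 3 h, MDA-MD-231 V50 6 h or MDA-MD-231 DMSO library gave 2628, 2730 and 2807 genes.

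SY200/V50 changed more genes than either agent alone, among them MCL1, MYC and SOX9. MCL1, which protects cells from apoptosis, fell by 2.41 ± 0.35 (edgeR BH-adjusted p = 3.23e-05), the oncogene MYC fell by 2.25 ± 0.39 (edgeR BH-adjusted p = 0.000156) and SOX9 fell by 3.62 ± 0.24 (edgeR BH-adjusted p = 6.13e-08). MYC was chosen after its value was seen. FOXQ1 (-4.19 ± 0.38), the zinc finger gene ZNF281 (-3.77 ± 0.35), DKK1 (-3.77 ± 0.33) and DUSP5 (-3.70 ± 0.32) had the largest falls, with edgeR BH-adjusted p of at most 5.69e-07. HEXIM1 was at -2.31 ± 0.16 and MEPCE at -2.64 ± 0.17. CDK7 mRNA fell by 1.63 ± 0.21 (edgeR BH-adjusted p = 1.05e-05) and CDK9 mRNA fell by 0.87 ± 0.21 (edgeR BH-adjusted p = 0.00213), whereas CDK1 was at -0.23 ± 0.14 (edgeR BH-adjusted p = 0.173), and passed at -0.39 without the MDA-MD-231 SY200/V50 12 h library. Among the largest rises were LINC00641 (2.48 ± 0.34), the chloride channel regulator CLCA2 (1.66 ± 0.28), the mitochondrial ribosomal RNA MT-RNR2 (1.62 ± 0.17) and AP2B1P1 (3.34 ± 0.65), a pseudogene whose counts can hold reads of its parent gene. CLCA2 lost its call without the MDA-MD-468 SY200/V50 6 h (1.57) or 12 h library (1.46) and under mitochondrial scaling.

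**Figure D1:**
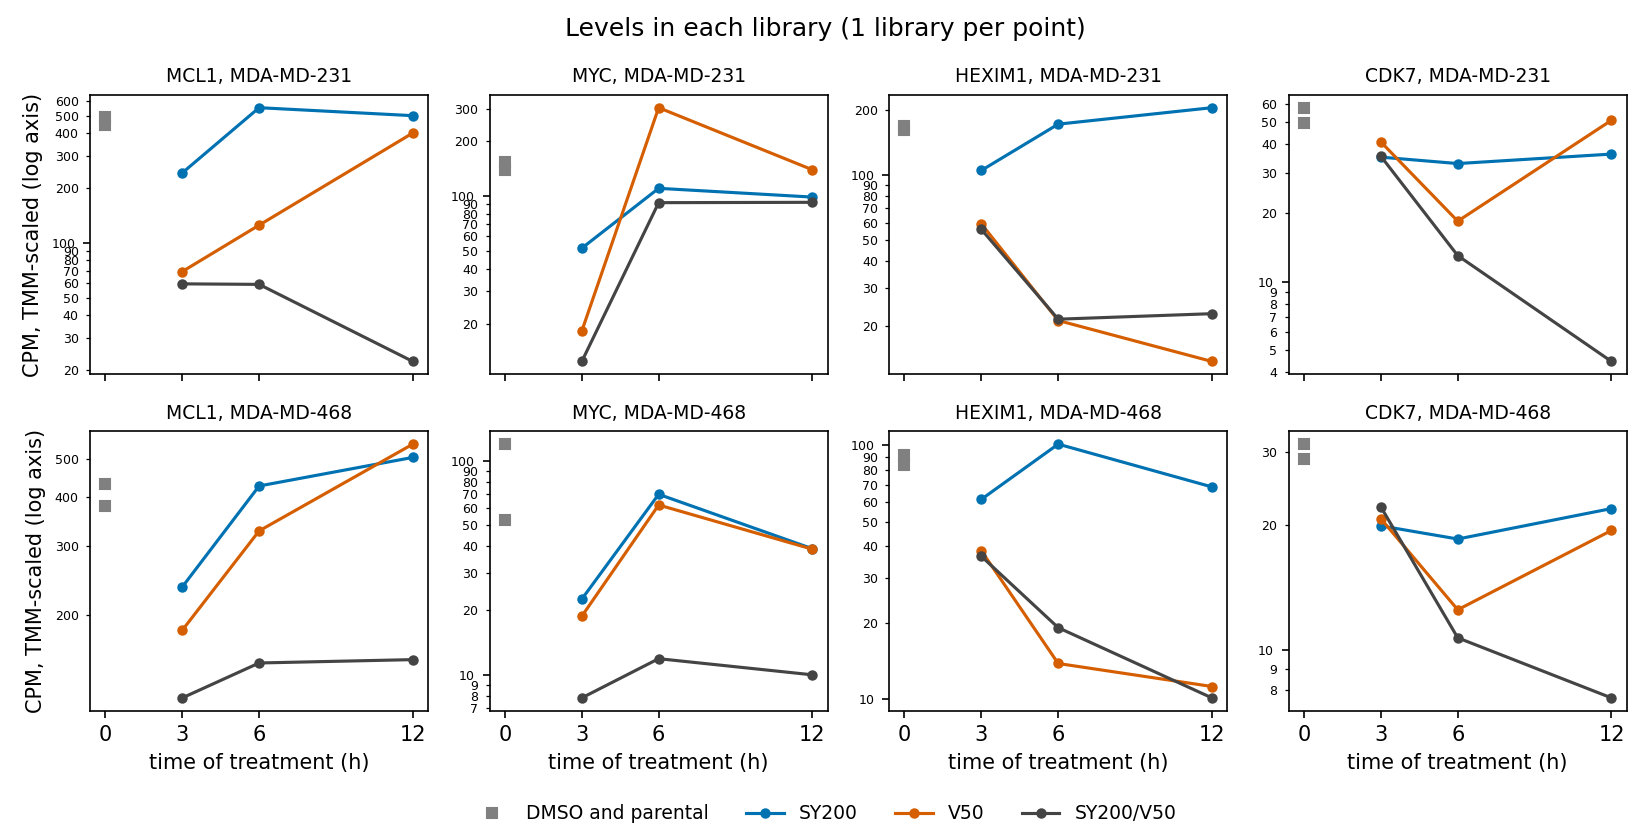
Level of MCL1, MYC, HEXIM1 and CDK7 (CPM, log axis) against hours of treatment, 1 library per point, in MDA-MD-231 and MDA-MD-468. With V50, MCL1 in MDA-MD-231 was at 69.5 CPM at 3 h and 401 CPM at 12 h, and with SY200/V50 at 59.5 and 22.3 CPM.

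Of 28 immediate-early genes 1 was higher and 17 lower with SY200/V50, also adjusted over the list alone (camera adjusted p = 1.69e-05, adjusted p = 0.183 with an estimated correlation), with KLF2 at -3.74 ± 0.40 and KLF4 at -2.31 ± 0.23. Anti-apoptotic genes had 1 of 10 members higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.0842 with an estimated correlation). BCL2 was at -1.07 ± 0.16 and BIRC3 at -1.48 ± 0.21, while BIRC5, which encodes survivin, rose by 0.54 ± 0.09 on the TMM scale and was at -0.89 on the mitochondrial scale. Pro-apoptotic genes fell as well, with 3 of 20 higher and 12 lower, also adjusted over the list alone (camera adjusted p = 0.00686, adjusted p = 0.0628 with an estimated correlation), led by BBC3 (-2.76 ± 0.40), whose product PUMA is a p53-driven killer protein. Of 24 p53 targets 0 were higher and 16 lower, and 2 and 16 adjusted over the list alone (camera adjusted p = 1.69e-05, adjusted p = 0.0508 with an estimated correlation), among them MDM2 (-1.38 ± 0.13), the negative regulator of p53. The elongation and P-TEFb list had 4 of 31 members higher and 15 lower, also adjusted over the list alone (camera adjusted p = 0.00134, adjusted p = 0.0772 with an estimated correlation), with CDK12, another kinase of RNA polymerase II that was chosen after its value was seen, at -1.72 ± 0.24. Oncogenic transcription factors and receptors had 2 of 32 higher and 16 lower, and 2 and 17 adjusted over the list alone (camera adjusted p = 0.000163, adjusted p = 0.0842 with an estimated correlation), with the WNT receptor FZD7 at -2.86 ± 0.22. YAP and TEAD targets had 3 of 23 higher and 14 lower, and 3 and 15 adjusted over the list alone (camera adjusted p = 0.00371, adjusted p = 0.157 with an estimated correlation). Zinc finger genes had 11 of 495 higher and 358 lower, and 12 and 368 adjusted over the list alone (camera adjusted p = 1.75e-26, adjusted p = 0.0842 with an estimated correlation), with ZNF792 at -4.45 ± 0.34 and ZNF526 at -3.50 ± 0.24.

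G2 and mitosis genes had 3 of 28 members higher and 15 lower with SY200/V50, and 3 and 16 adjusted over the list alone (camera adjusted p = 0.00263, adjusted p = 0.204 with an estimated correlation). The spindle checkpoint kinase gene TTK was at -1.39 ± 0.14 and AURKA at -1.33 ± 0.13. Inflammatory NF-kB genes had 1 of 25 higher and 6 lower, and 0 and 5 adjusted over the list alone (camera adjusted p = 0.0488, adjusted p = 0.499 with an estimated correlation). On the other side stood cytosolic ribosomal protein genes, 75 of 78 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 1.3e-25, adjusted p = 0.195 with an estimated correlation). With them stood nuclear oxidative phosphorylation genes, 46 of 49 higher and 0 lower (camera adjusted p = 1.82e-17, adjusted p = 0.183 with an estimated correlation). Their medians of 0.76 and 0.70 became -0.67 and -0.73 under mitochondrial scaling, so their direction depends on that choice. Several lists moved in both directions and were not called by camera with SY200/V50. Homologous recombination and Fanconi genes had 5 of 32 higher and 10 lower, 5 and 11 adjusted over the list alone (camera adjusted p = 0.112), with FANCF at -2.59 ± 0.24, BRCA2 at -1.31 ± 0.18 and FANCI at 0.74 ± 0.10, or -0.69 on the mitochondrial scale. Heat shock genes had 6 of 18 higher and 9 lower (camera adjusted p = 0.0966), with DNAJB1 at -1.79 ± 0.17 and HSPA1A, which shares reads with its near-identical copy HSPA1B, at -2.30 ± 0.23. Integrated stress response genes had 5 of 24 higher and 9 lower (camera adjusted p = 0.211), and cholesterol synthesis genes had 7 of 23 higher and 7 lower (camera adjusted p = 0.996). The counts of these 3 lists were no different adjusted over the list alone. Interferon-stimulated genes had 5 of 29 higher and 6 lower, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.82). With SY200/V50 9114 of 18911 genes passed the edgeR test, 4532 higher and 4582 lower, of which 1113 rose and 2706 fell more than 2-fold. Under mitochondrial scaling 171 genes were higher and 15661 lower.

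With V50 many genes low at 3 h were near the control at 12 h, and with SY200/V50 they stayed low. All controls are of 0 h, so changes against control mix treatment and time. MCL1 was lower with V50 at 3 h (edgeR BH-adjusted p = 0.0378), at -1.12 at 6 h (edgeR BH-adjusted p = 0.101) and at 0.04 at 12 h (edgeR BH-adjusted p = 0.964). With SY200/V50 it was at -2.40 at 3 h (edgeR BH-adjusted p = 0.00999) and -2.59 at 12 h (edgeR BH-adjusted p = 0.000713). MCL1 rose from 3 to 12 h with V50 (2.01 ± 0.55, edgeR BH-adjusted p = 0.0235), and the difference of this change between SY200/V50 and V50 did not pass the test (-2.20 ± 0.76, edgeR BH-adjusted p = 0.0633). MYC fell by 2.48 with V50 at 3 h (edgeR BH-adjusted p = 0.0242) and was at -0.62 at 12 h, against -3.52 and -1.64 with SY200/V50. SOX9 went from -2.59 to -1.36 with V50 and from -3.27 to -4.05 with SY200/V50, a difference of -2.01 ± 0.52 (edgeR BH-adjusted p = 0.0206). HEXIM1 did not recover and went from -1.33 at 3 h through -2.82 at 6 h to -3.27 at 12 h with V50, a further fall of -1.93 ± 0.26 (edgeR BH-adjusted p = 0.000831). CDK7 mRNA was at -2.62 after 12 h of SY200/V50 (edgeR BH-adjusted p = 9.03e-06). These genes were chosen for the time course after their values were seen. At 3 h the calls of MCL1, MYC and HEXIM1 with V50 were lost without either V50 3 h library (MCL1 at -1.60 and -2.43, MYC at -1.86 and -3.46, HEXIM1 at -1.27 and -1.43), and that of MCL1 was also lost without the MDA-MD-231 DMSO (-1.80) or parental library (-1.87). The calls of MCL1 with SY200/V50 at 3 h and from 3 to 12 h of V50 were lost without any of the 2 or 4 treated libraries they rest on. Without the MDA-MD-468 SY200/V50 12 h library the difference for MCL1 passed at -3.87. The difference for SOX9 was lost without any of 5 libraries (-1.78 to -2.04), and its V50 call at 12 h without either V50 12 h library (-1.59 and -1.17). The call of MYC was lost with SY200/V50 without the MDA-MD-231 3 h library (-3.15) at 3 h and the MDA-MD-468 parental (-1.28) or 12 h library (-1.09) at 12 h.

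**Figure D2:**
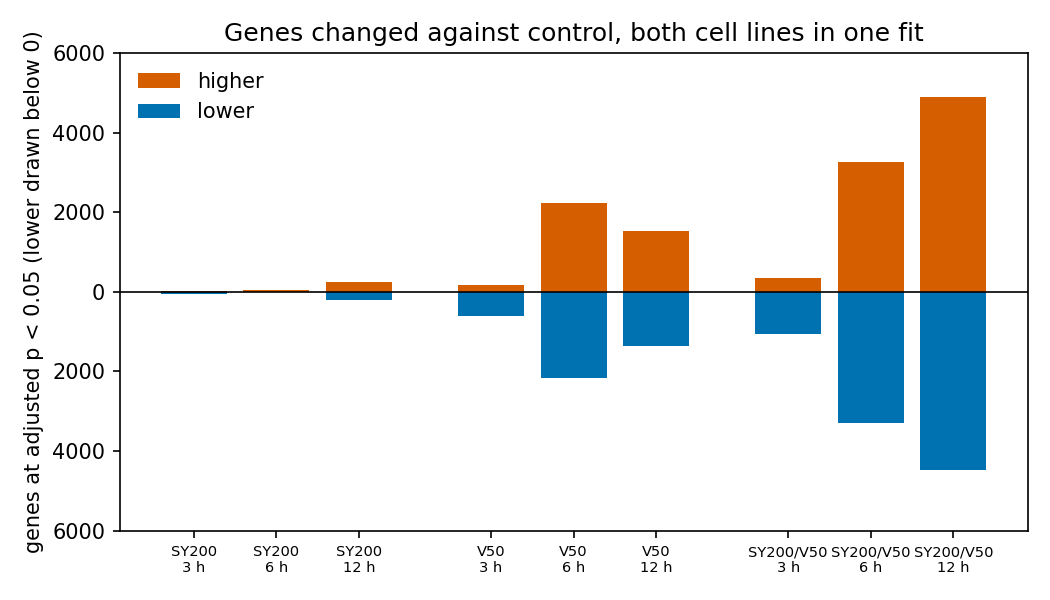
Number of genes past edgeR BH-adjusted p under 0.05 against control, drawn above 0 when higher and below 0 when lower, for each treatment at 3, 6 and 12 h with both lines in a single fit. SY200/V50 rose from 1426 genes at 3 h to 9374 at 12 h, while V50 was highest at 6 h with 4421.

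Of the 616 genes lower with V50 at 3 h, 69 (11.2%) were still lower at 12 h, 32 were higher and 515 did not pass, and 431 were called as rising between 3 and 12 h. Their median went from -1.67 at 3 h through -1.30 at 6 h to -0.07 at 12 h. With SY200/V50, 579 (94%) of the same genes were lower at 12 h and the median was -2.33. With SY200 the count was 6 (0.974%) and the median went from -0.92 at 3 h to 0.13 at 12 h. Of the 1071 genes lower with SY200/V50 itself at 3 h, 967 (90.3%) were lower at 12 h. Under mitochondrial scaling 7691 genes were lower with V50 at 3 h, and 75.3% of them stayed lower at 12 h with V50 and 99.6% with SY200/V50. Without the MDA-MD-231 V50 3 h library 22 genes were followed, with 31.8% and 100% still lower, and without the MDA-MD-468 V50 3 h library 96 genes, with 17.7% and 93.8%. Without the MDA-MD-231 V50 12 h library 14 of 622 genes (2.25%) were still lower with V50, and without the MDA-MD-231 SY200/V50 12 h library 590 of 814 (72.5%) with SY200/V50. All these values share the control libraries. In 8 simulated data sets with no effect, 75.4% of the genes lowest at 3 h lay below control at 12 h with V50 and 76.1% with SY200/V50, against 53.9% and 98.7% observed. Lists drawn independently would share 44.3 lower genes with V50 and 146 with SY200/V50, against 69 and 579 observed.

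**Figure D3:**
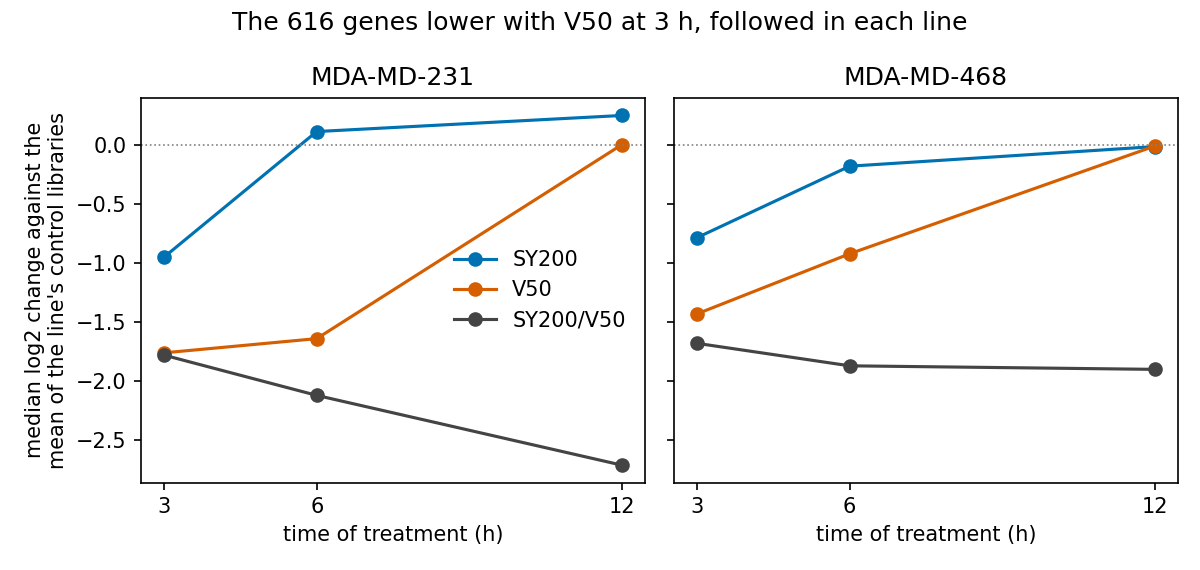
Median log2 change, against the mean of each line's control libraries, of the 616 genes lower with V50 at 3 h, at 3, 6 and 12 h of each treatment. At 12 h the medians were 0 in MDA-MD-231 and -0.01 in MDA-MD-468 with V50, and -2.71 and -1.90 with SY200/V50.

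Zinc finger and immediate-early genes were among those that returned. Zinc finger genes had 0 of 495 members higher and 139 lower with V50 at 3 h, and 1 and 273 adjusted over the list alone (camera adjusted p = 5.94e-45, adjusted p = 0.0548 with an estimated correlation). Between 3 and 12 h of V50, 259 of them rose and 5 fell, 329 and 17 adjusted over the list alone (camera adjusted p = 4.63e-38, adjusted p = 0.224 with an estimated correlation). Immediate-early genes had 0 of 28 higher and 9 lower with V50 at 3 h, 12 lower adjusted over the list alone (camera adjusted p = 1.33e-09, adjusted p = 0.0882 with an estimated correlation), and 8 rose and 0 fell between 3 and 12 h, 13 and 0 adjusted over the list alone (camera adjusted p = 4.21e-07, adjusted p = 0.244 with an estimated correlation). From 3 to 12 h the edgeR test called 368 genes with SY200 (185 up, 183 down), 2423 with V50 (1508 up, 915 down) and 3461 with SY200/V50 (1810 up, 1651 down). The change from 3 to 12 h differed between SY200/V50 and V50 for 2441 genes, 873 higher and 1568 lower with the combination, and between SY200/V50 and SY200 for 2791, 1247 higher and 1544 lower. Among zinc finger genes the former difference was positive for 2 and negative for 167, 6 and 241 adjusted over the list alone (camera adjusted p = 2.84e-28, adjusted p = 0.13 with an estimated correlation). Each single time rests on 1 library per line. The counts at 3, 6 and 12 h were 80, 50 and 460 for SY200, 776, 4421 and 2876 for V50, and 1426, 6565 and 9374 for SY200/V50, for which the drawing of counts shows both directions. Without the MDA-MD-231 or the MDA-MD-468 library of the time itself the counts were 7 and 5, 0 and 97, and 56 and 3 for SY200, 41 and 99 at 3 h and 645 and 2668 at 6 h for V50, and 181 and 169 at 3 h and 2834 and 3584 at 6 h for SY200/V50. At 12 h V50 gave 443 without the MDA-MD-231 library. Without the MDA-MD-231 DMSO library V50 and SY200/V50 gave 478 and 879 at 3 h, and V50 gave 492 without the MDA-MD-468 DMSO library. SY200 ranged further from 20 to 153 at 3 and 6 h, but 5 at 6 h without the MDA-MD-468 DMSO library, and from 151 without the MDA-MD-468 parental to 752 without the MDA-MD-468 SY200/V50 12 h library at 12 h.

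The counts between 3 and 12 h rest on these single libraries too. For SY200 the count was 0 without either SY200 3 h library or the MDA-MD-468 SY200 12 h library, 10 without the MDA-MD-231 SY200 12 h library, 155 to 166 without any V50 3 h, SY200/V50 3 h or SY200/V50 6 h library, and 748 and 757 without the SY200/V50 12 h libraries. For V50 it was 226, 487 and 752 without the MDA-MD-231 V50 3 h, MDA-MD-231 V50 12 h and MDA-MD-468 V50 3 h library, and for SY200/V50 1020 and 1470 without the MDA-MD-231 and MDA-MD-468 SY200/V50 3 h library. The difference from V50 gave 525 to 1509 genes without any V50 or SY200/V50 library of 3 or 12 h except the MDA-MD-468 SY200/V50 12 h library, which gave 3816. The difference from SY200 gave 705 to 1262 without either 3 h library of SY200 or SY200/V50 or the MDA-MD-231 12 h library of either.

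Compared with V50 alone, the combination further lowered some immediate-early, anti-apoptotic, p53 target and mitotic mRNAs, as lists only with the preset correlation. JUN fell by 1.81 ± 0.28 (edgeR BH-adjusted p = 0.000577), FOSL1 fell by 1.43 ± 0.26 (edgeR BH-adjusted p = 0.00164) and MCL1 fell by 1.39 ± 0.31 (edgeR BH-adjusted p = 0.00565). The mitotic histone kinase HASPIN (-2.07 ± 0.22), ZNF627 (-2.26 ± 0.31), ZNF526 (-2.12 ± 0.23) and C15orf39 (-2.21 ± 0.20) were among the largest falls, with edgeR BH-adjusted p of at most 0.000245. CDK7 fell by 0.91 ± 0.19 (edgeR BH-adjusted p = 0.00396) and CDK9 fell by 0.74 ± 0.19 (edgeR BH-adjusted p = 0.0111), lost at -0.64 without the MDA-MD-468 V50 6 h library. Immediate-early genes had 0 of 28 higher and 13 lower, 16 lower adjusted over the list alone (camera adjusted p = 1.82e-08, adjusted p = 0.12 with an estimated correlation). Anti-apoptotic genes had 1 of 10 higher and 5 lower, 1 and 6 adjusted over the list alone (camera adjusted p = 0.00933, adjusted p = 0.118 with an estimated correlation). G2 and mitosis genes had 0 of 28 higher and 10 lower, also adjusted over the list alone (camera adjusted p = 0.000201, adjusted p = 0.152 with an estimated correlation), with TTK at -1.15 ± 0.13 and AURKA at -0.98 ± 0.12. For p53 targets the counts were 1 of 24 higher and 11 lower, 2 and 11 adjusted over the list alone (camera adjusted p = 0.000632, adjusted p = 0.118 with an estimated correlation). The largest rises were small, such as the collagen receptor gene MRC2 (0.78 ± 0.22) and the collagen gene COL6A1 (0.73 ± 0.22), and were not past the threshold under mitochondrial scaling or without any of 3 (MRC2) or 7 (COL6A1) libraries. In all, 3766 genes passed the edgeR test, 1422 higher and 2344 lower, against 2214 and 2193 with DESeq2's size factors and 8 and 6599 with mitochondrial scaling. Without the MDA-MD-468 V50 6 h library 1637 genes were called. The count was 2392 and 2449 without the V50 3 h library of MDA-MD-231 and MDA-MD-468, 2091 and 2309 without the MDA-MD-231 SY200/V50 6 h and 12 h library and 2316 without the MDA-MD-468 SY200/V50 3 h library.

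Few genes passed between the combination and V50 at 3 and 6 h, many at 12 h. In simulation 7.46% of 2-fold changes passed at 3 h. At 3 h the edgeR test called 1 gene (164 at an unadjusted p under 0.05, 0 with DESeq2), the noncoding RNA RP11-309L24.6 at -4.70 ± 0.57. At 6 h it called 2 (1085 unadjusted, 61 with DESeq2), C15orf39 at -2.48 ± 0.35 and the small nuclear RNA RNU5A-1 at -4.13 ± 0.59, all 3 named after their values were seen. The 3 h gene was lost without the MDA-MD-231 V50 3 h, MDA-MD-231 SY200/V50 3 h or MDA-MD-468 DMSO library. The 6 h count was 23 without the MDA-MD-231 V50 6 h library, 7 without either SY200/V50 12 h library, 1 without the MDA-MD-468 V50 6 h library and 0 without either SY200/V50 6 h library. At 12 h it called 7102, 3656 higher and 3446 lower, with 3631 and 4530 without the MDA-MD-231 SY200/V50 12 h and MDA-MD-468 V50 12 h library. Against SY200 the combination differed at all times, with 19 genes at 3 h, all lower, among them the feedback regulators SOCS3 (-3.21 ± 0.44) and DUSP6 (-2.35 ± 0.43) and the transcription factor KLF4 (-2.25 ± 0.38), also chosen after their values were seen. The 19 became 0 without the MDA-MD-231 SY200 3 h or either SY200/V50 3 h library, 4, 6 and 11 without the MDA-MD-231 DMSO, MDA-MD-468 SY200 3 h and MDA-MD-468 parental library, and 32 without either V50 3 h library. Against SY200 3480 genes passed at 6 h, with 989, 671 and 1135 without the MDA-MD-231 SY200 6 h, MDA-MD-231 SY200/V50 6 h and MDA-MD-468 SY200/V50 6 h library. At 12 h 8566 passed, with 5389 and 5598 without the MDA-MD-231 SY200 and SY200/V50 12 h library. Over the times the combination was below SY200 for IER5L (-3.77 ± 0.35), BAMBI (-3.55 ± 0.37), ZNF627 (-3.49 ± 0.32) and FOXQ1 (-3.47 ± 0.36), with edgeR BH-adjusted p of at most 2.32e-06. CDK7 was at -1.03 ± 0.19 and CDK9 at -0.89 ± 0.19. Of 24 p53 targets 0 were higher and 17 lower than with SY200, 2 and 18 adjusted over the list alone (camera adjusted p = 1.81e-06, adjusted p = 0.0328 with an estimated correlation). Between the combination and SY200 8693 genes passed the edgeR test, 4496 higher and 4197 lower, and 70 and 13575 under mitochondrial scaling.

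Whether the combination did more than the sum of its parts was tested on the log2 scale. Zinc finger genes had 5 of 495 members above the sum of the single effects and 79 below it, 13 and 173 adjusted over the list alone (camera adjusted p = 1.12e-16, adjusted p = 0.418 with an estimated correlation). Immediate-early genes had 1 of 28 below the sum (camera adjusted p = 2.4e-06, adjusted p = 0.418 with an estimated correlation), and elongation and P-TEFb genes 4 of 31, 7 adjusted over the list alone. In all, 953 genes departed from the sum, 258 above and 695 below, with 347 and 602 when DESeq2's size factors were used. It was 2667 without the MDA-MD-468 SY200/V50 12 h and 1442 without the MDA-MD-468 SY200 6 h library, and between 286 and 608 without any other library except the MDA-MD-231 DMSO, MDA-MD-231 V50 6 h, MDA-MD-468 SY200 12 h and MDA-MD-468 V50 12 h libraries, which gave 781 to 1144.

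The lines were compared for each treatment. Heat shock genes, which encode chaperones, responded more negatively in MDA-MD-468 than in MDA-MD-231 as a list, with 0 of 18 genes past the threshold over all genes and 8 lower with V50 and 10 lower with SY200/V50 adjusted over the list alone (camera adjusted p = 7.61e-07 and 2.14e-06, adjusted p = 0.315 and 0.346 with an estimated correlation). Immediate-early genes had a more positive V50 effect in MDA-MD-468, with 0 of 28 over all genes and 8 higher adjusted over the list alone (camera adjusted p = 0.00113, adjusted p = 0.443 with an estimated correlation). Over all genes edgeR called 0 genes for SY200, V50 and SY200/V50, with 1048, 1873 and 3009 at an unadjusted p under 0.05, and DESeq2 called 33, 120 and 421. For SY200/V50 the count was 278 and 277 without the SY200/V50 3 h library of MDA-MD-231 and MDA-MD-468, 70 and 71 without their V50 12 h library, 16 without the MDA-MD-468 DMSO library, and 3 and 2 without either SY200 3 h and either V50 6 h library. For SY200 it was 4 without the MDA-MD-468 DMSO and 1 without either SY200/V50 12 h library, and for V50 2 and 1 without the MDA-MD-231 and MDA-MD-468 V50 12 h library.

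DMSO and parental libraries differed at 7 genes, all lower with DMSO. They included the hyaluronan synthase gene HAS2 (-4.00 ± 0.37, edgeR BH-adjusted p = 0.000185), DKK1 (-1.67 ± 0.27, edgeR BH-adjusted p = 0.0402) and the alkaline phosphatase gene ALPP (-1.67 ± 0.24, edgeR BH-adjusted p = 0.0151), named after their values were seen. The count was 1540 at an unadjusted p under 0.05 and 122 with DESeq2, 0 without the MDA-MD-231 DMSO or the MDA-MD-468 parental library, 20 without the MDA-MD-231 parental library, 29 without either SY200 6 h library, 12 without either SY200/V50 12 h library and 4 without any 3 h library.

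The knockout part asked what loss of each kinase gene does over days. Each targeted mRNA was lower in its own knockout libraries at both times. CDK1 (chromosome 10, 60778331 to 60794852) was at 178 and 283 CPM with the empty vector and at 81.1 CPM (45.6%) and 84.5 CPM (29.9%) in CDK1 KO at 72 and 96 h. CDK7 (chromosome 5, 69234795 to 69277430) was at 49 and 66.7 CPM with the empty vector, at 15.2 CPM (31%) and 13.7 CPM (20.5%) in CDK7 KO and at 15.6 CPM (31.8%) and 17.1 CPM (25.6%) in CDK7/9 KO. CDK9 (chromosome 9, 127785679 to 127790787) was at 70.5 and 62.2 CPM with the empty vector, at 33.1 CPM (47%) and 36.2 CPM (58.2%) in CDK9 KO and at 34.2 CPM (48.5%) and 36.6 CPM (58.8%) in CDK7/9 KO. In the parental library the levels were 84.5, 56.5 and 64.1 CPM. In the knockout libraries of the other genes CDK1 was at 140 to 182 CPM, CDK7 at 44.8 to 48.8 CPM and CDK9 at 66.8 to 73.1 CPM. Guide positions are not given, and a 3' tag outside the deleted part would check nothing, so these levels do not measure how many cells lost the gene.

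**Figure D4:**
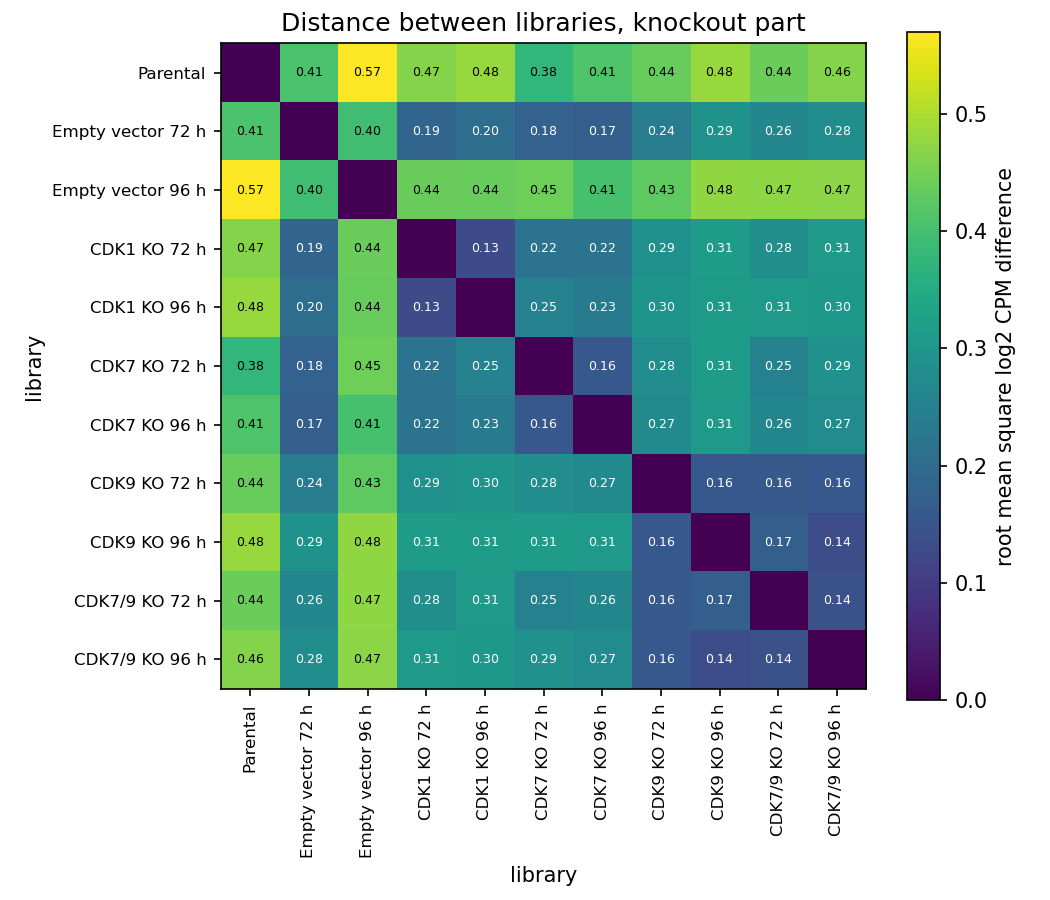
Root mean square difference in log2 CPM over 9821 genes between each pair of the 11 libraries of the knockout part. The empty vector library at 96 h lay 0.396 to 0.476 from the other empty vector and knockout libraries, which lay 0.132 to 0.313 from each other.

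The empty vector library at 96 h stood apart from all others, as the plot of distances shows, and each knockout comparison rests on 2 empty vector libraries. Relative to the 72 h empty vector its mitochondrial mRNAs had a median of -0.72, below all of 10000 random lists matched on expression, and its G2 and mitosis genes a median of 0.27, at the 99.9th percentile. Gene tests below were repeated without it, unlike the comparison with inhibitors. A lone empty vector is assumed to vary like the knockout groups. All knockout fits had 4 residual degrees of freedom.

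CDK1 KO raised some inflammatory and immediate-early mRNAs, as lists only with the preset correlation, and none under mitochondrial scaling. IL6 rose by 1.34 ± 0.18 (edgeR BH-adjusted p = 0.0161), the complement gene C3 by 1.31, the adhesion molecule ICAM1 by 0.97 ± 0.11 (edgeR BH-adjusted p = 0.0118) and EGR1 by 0.97 ± 0.12 (edgeR BH-adjusted p = 0.0144). FLG rose by 1.89 ± 0.27 and ALPP by 1.29 ± 0.15, and CDK1 itself fell by 1.46 ± 0.17 (edgeR BH-adjusted p = 0.0137). Of 25 inflammatory NF-kB genes 8 were higher and 0 lower, 20 higher adjusted over the list alone (camera adjusted p = 9.65e-24, adjusted p = 0.172 with an estimated correlation). Of 28 immediate-early genes 4 were higher and 0 lower, 12 and 0 adjusted over the list alone (camera adjusted p = 2.88e-10, adjusted p = 0.216 with an estimated correlation). DNA replication and E2F genes had 0 of 36 past the threshold over all genes and 16 lower adjusted over the list alone (camera adjusted p = 6.57e-09, adjusted p = 0.172 with an estimated correlation). Homologous recombination and Fanconi genes had 0 of 32, and 3 lower adjusted over the list alone (camera adjusted p = 0.000229, adjusted p = 0.221 with an estimated correlation). The helicase gene DNA2 fell by 0.72 (edgeR BH-adjusted p = 0.0353). In all, edgeR called 59 genes, 54 higher and 5 lower, and DESeq2 412, while under mitochondrial scaling edgeR called 0. Without the 96 h empty vector library 418 genes were called, 57 of the 59 among them, and without the 72 h one 6976. Without CDK1 KO at 72 and 96 h 1 and 0 genes were called, and without either CDK7 KO library 0. Without CDK9 KO at 72 and 96 h the counts were 5 and 23, and without CDK7/9 KO 15 and 16. Each gene named here lost its call without either CDK1 KO or either CDK7 KO library, except C3 without CDK1 KO at 72 h.

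CDK7 KO changed few genes, but many without the low-count filter. CDK7 fell by 1.98 ± 0.14 (edgeR BH-adjusted p = 0.000421), H2BC12 rose by 1.09 ± 0.14 and the desaturase gene SCD by 0.86 ± 0.11 (both edgeR BH-adjusted p = 0.0483). They were among the 4 of 16783 genes that passed, and these rises did not pass under mitochondrial scaling. CDK1 was at -0.64 (edgeR BH-adjusted p = 0.18) and CDK9 at 0.04 (edgeR BH-adjusted p = 0.85). Histone genes had 1 of 22 higher and 0 lower, 12 and 1 adjusted over the list alone (camera adjusted p = 1.49e-12, adjusted p = 0.156 with an estimated correlation). G2 and mitosis genes had 0 of 28 past the threshold over all genes and 19 lower adjusted over the list alone (camera adjusted p = 1.49e-12, adjusted p = 0.188 with an estimated correlation). For snoRNA host and nuclear noncoding RNAs the values were 0 of 21 and 11 lower (camera adjusted p = 4.08e-10, adjusted p = 0.156 with an estimated correlation). Both these lists were higher in the 96 h than in the 72 h empty vector library. Cholesterol synthesis genes had 0 of 23 past the threshold and 5 higher adjusted over the list alone (camera adjusted p = 0.000537, adjusted p = 0.156 with an estimated correlation), with a median of 0.13 that became -0.20 under mitochondrial scaling. The count of 4 compares with 199 with DESeq2, 235 without the 96 h empty vector library, which kept all 4, and 6239 without the 72 h one. It was 1 and 2 without CDK7 KO at 72 and 96 h and 2 without any CDK9 KO or CDK7/9 KO library. H2BC12 (0.86 to 1.26) and SCD (0.80 to 0.89) lost their calls without any of the 8 knockout libraries.

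CDK9 KO lowered HEXIM1 and some interferon and mitotic mRNAs and raised mitochondrial mRNAs. HEXIM1 fell by 0.90 ± 0.10, CDK9 by 0.93 ± 0.11 and IL11 by 1.15 ± 0.11 (each edgeR BH-adjusted p = 0.00409). The methyltransferase gene NNMT fell by 1.51 ± 0.23 (edgeR BH-adjusted p = 0.00773), IL6 fell by 0.96 (edgeR BH-adjusted p = 0.0213) and the centromere motor gene CENPE fell by 0.83 ± 0.15 (edgeR BH-adjusted p = 0.0149). CCNT1, which encodes the cyclin partner of CDK9, rose by 0.45 ± 0.09 (edgeR BH-adjusted p = 0.0197) and was at -0.37 under mitochondrial scaling. CDK7 (-0.25) and CDK1 (-0.41) did not pass. G2 and mitosis genes had 0 of 28 higher and 7 lower, 22 lower adjusted over the list alone (camera adjusted p = 7.06e-09, adjusted p = 0.364 with an estimated correlation). Interferon-stimulated genes had 0 of 28 higher and 9 lower, 10 adjusted over the list alone (camera adjusted p = 0.000198, adjusted p = 0.364 with an estimated correlation), such as IFIT3 (-0.74) and OASL (-0.62 ± 0.12). This list had a median of 0.22 in the 96 h empty vector library relative to the 72 h one, at the 95th percentile of random lists. Without that library 9 interferon-stimulated and 11 G2 and mitosis genes were lower and 12 mitochondrial mRNAs higher, with medians of -0.29, -0.24 and 0.53, and IL6, CENPE and IFIT3 were at -0.58, -0.51 and -0.48. Inflammatory NF-kB genes had 0 of 25 higher and 4 lower, 6 lower adjusted over the list alone (camera adjusted p = 0.00147, adjusted p = 0.414 with an estimated correlation). Cholesterol synthesis genes had 0 of 23 higher and 5 lower, 7 adjusted over the list alone (camera adjusted p = 7.08e-05, adjusted p = 0.364 with an estimated correlation), with HMGCS1 at -0.65 ± 0.11. Mitochondrial mRNAs had 10 of 13 higher, 12 adjusted over the list alone (camera adjusted p = 3.32e-13, adjusted p = 0.364 with an estimated correlation). Histone genes had 7 of 22 higher and 1 lower, 10 and 2 adjusted over the list alone (camera adjusted p = 0.000167, adjusted p = 0.364 with an estimated correlation), but their median of 0.53 became -0.27 under mitochondrial scaling. Zinc finger genes had 33 of 467 higher and 4 lower, 31 and 4 adjusted over the list alone (camera adjusted p = 0.000142, adjusted p = 0.364 with an estimated correlation), and their median of 0.15 became -0.68. Of all genes 1369 passed the edgeR test, 728 higher and 641 lower (67 and 11344 under mitochondrial scaling). The count was 0 without the CDK9 KO 96 h library, where every gene named here lost its call, 219 without the 72 h one, 450 to 613 without any other knockout library, 2144 without the 96 h empty vector and 6984 without the 72 h one.

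CDK7/9 KO lowered CDK7, CDK9, HEXIM1 and some interferon, inflammatory and mitotic mRNAs. CDK7 fell by 1.81 ± 0.14 (edgeR BH-adjusted p = 0.000975), CDK9 by 0.90 ± 0.11 and HEXIM1 by 0.77 ± 0.10 (both edgeR BH-adjusted p = 0.00387). CDK1 was at -0.59 ± 0.17 (edgeR BH-adjusted p = 0.0478). The interferon genes OASL (-1.10 ± 0.12) and IFIT1 (-1.20 ± 0.19), the cytokine genes IL24 (-1.20 ± 0.15) and CXCL8 (-1.35 ± 0.27) and the kinetochore gene SPC25 (-1.22 ± 0.15) fell, with edgeR BH-adjusted p of at most 0.0157. Without the 96 h empty vector CDK1, OASL, IFIT1, CXCL8 and SPC25 were at -0.19, -1.18, -0.82, -0.7 and -0.98. The antigen presentation gene MR1 rose by 1.22 ± 0.11 and the histone gene H2BC5 by 1.23 ± 0.11 (both edgeR BH-adjusted p = 0.00184). Interferon-stimulated genes had 0 of 28 higher and 10 lower, also adjusted over the list alone (camera adjusted p = 8.85e-08, adjusted p = 0.211 with an estimated correlation). Inflammatory NF-kB genes had 0 of 25 higher and 9 lower, 13 lower adjusted over the list alone (camera adjusted p = 4.15e-07, adjusted p = 0.211 with an estimated correlation). G2 and mitosis genes had 0 of 28 higher and 17 lower, 22 adjusted over the list alone (camera adjusted p = 1.16e-11, adjusted p = 0.221 with an estimated correlation). Cytosolic ribosomal protein genes had 0 of 78 higher and 23 lower, 38 adjusted over the list alone (camera adjusted p = 2.35e-12, adjusted p = 0.211 with an estimated correlation). In all, 1903 genes passed the edgeR test, 960 higher and 943 lower (78 and 11060 under mitochondrial scaling). The count was 0 and 2 without the 72 and 96 h CDK7/9 KO library, 787 to 925 without either CDK1 KO or CDK7 KO library, and 7329 without the 72 h empty vector. Each named gene lost its call without either CDK7/9 KO library, except CDK7 without the 96 h one, and CDK1 lost its call without any library other than the 72 h empty vector.

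Against CDK7 KO, the double knockout had lower CDK9 (-0.94 ± 0.11, edgeR BH-adjusted p = 0.00268) and HEXIM1 (-0.92 ± 0.10, edgeR BH-adjusted p = 0.0022), with calls lost without either CDK7/9 KO library or the CDK7 KO 96 h library. Cholesterol synthesis genes had 0 of 23 higher and 2 lower, 5 lower adjusted over the list alone (camera adjusted p = 1.13e-06, adjusted p = 0.227 with an estimated correlation), and YAP and TEAD targets 0 of 23 and 5, 7 lower adjusted over the list alone (camera adjusted p = 1.44e-05, adjusted p = 0.29 with an estimated correlation). There 722 genes passed, 368 higher and 354 lower (43 and 1746 under mitochondrial scaling). The count was 0 without either CDK7/9 KO library, 24 and 1 without CDK7 KO at 72 and 96 h, 267 to 424 without any CDK1 KO or CDK9 KO library, and 4135 and 4120 without the 72 and 96 h empty vector. Against CDK9 KO edgeR called 1 gene, CDK7 (-1.56 ± 0.14, edgeR BH-adjusted p = 0.00461), with 442 at an unadjusted p under 0.05 and 4 with DESeq2. That count was 69 without the 96 h and 76 without the 72 h empty vector library, 2 without the CDK9 KO 96 h library, and 0 without either CDK7/9 KO library or the CDK9 KO 72 h library. Cholesterol synthesis genes (0 of 23 past the threshold, camera adjusted p = 8.26e-07, adjusted p = 0.203 with an estimated correlation) and histone genes (0 of 22, camera adjusted p = 4.92e-06, adjusted p = 0.317 with an estimated correlation) were higher than in CDK9 KO as lists, with 0 also adjusted over the list alone. Immediate-early genes (0 of 28 past the threshold, 4 lower adjusted over the list alone, camera adjusted p = 3.15e-05), inflammatory NF-kB genes (0 of 25, 1 lower, camera adjusted p = 3.15e-05) and interferon-stimulated genes (0 of 28, 0 lower, camera adjusted p = 0.000145) were lower, each with an adjusted p of 0.317 with an estimated correlation.

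Inhibitor effects in MDA-MD-231 were set beside knockout effects across 16158 genes, which are not independent replicates. SY200 had a Pearson r of 0.292 with CDK7/9 KO and 0.275 with CDK9 KO, V50 had 0.139 and 0.133, and SY200/V50 had 0.0525 and 0.0452. With genes of at least 10 CPM the values for V50 were 0.0672 and 0.0671 and those for SY200/V50 0.0303 and 0.0171. With CDK7 KO alone r was 0.0892, -0.0399 and 0.0139, and with CDK1 KO 0.12, -0.034 and -0.00322. Genes called in the fit of both lines were counted next to those called in the knockouts. SY200 and CDK7/9 KO shared 93 called genes, 86 with the same sign (45 higher and 41 lower, against 8.1 and 10.4 for independent lists). V50 and CDK7/9 KO shared 488, 350 with the same sign (177 higher and 173 lower, against 94.3 and 124), and SY200/V50 and CDK7/9 KO shared 979, 565 with the same sign (320 higher and 245 lower, against 230 and 252). The parts used different controls, and the 96 h empty vector was kept here.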

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

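The swaps of library labels within line and time, and the test with separate controls, were chosen only after the results they measure were seen.

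The times differed within each treatment. Between 3 and 12 h 368 genes changed with SY200, 2423 with V50 and 3461 with SY200/V50 in the edgeR test of 12 h against 3 h, both lines in 1 fit. Leaving out the MDA-MD-231 V50 3 h library brought the V50 count to 226. Leaving out the MDA-MD-231 SY200/V50 3 h library brought that of SY200/V50 to 1020, and that of SY200 was 0 without either SY200 3 h library. The labels give no batch for the times, and the cause was not tested.

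Splits of the libraries into groups of the same sizes were tested in fits that take no account of time. For SY200 against control 77 genes were called with the real grouping. Of 100 splits, the real one included, 3 gave as many, and the highest other gave 620. That split took the 6 and 12 h SY200 libraries of both lines as the control, which points to the structure of the times. For V50 the values were 646 genes, 3 of 100 splits and 1240, with the V50 3 and 6 h libraries as the control. For SY200/V50 they were 6707, 2 of 100 and 7128, with the SY200/V50 6 and 12 h libraries as the control. Each real count was exceeded by another split. For SY200/V50 against SY200 it was 6153 genes, 1 of 100 and a highest other of 1, so no other split drawn came near the real count. For SY200/V50 against V50 it was 1 gene, 4 of 100 and a highest other of 1, and a count this small decides nothing. In the report's own fit, with labels swapped within line and time, SY200/V50 against SY200 gave 8693 genes, 1 of 32 swaps gave as many and the highest other gave 7695. SY200/V50 against V50 gave 3766, 1 of 32 and 3421. Both real counts were thus the highest of 32, but other swaps came close.

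For SY200/V50 against the sum of the single effects the fit without time called 5 genes, 15 of 100 splits gave as many and the highest other gave 3691. Swaps within line and time gave at least the real 953 genes in 7 of 40 cases, with a highest other of 8365. Other splits put the large effects of the treatments into this contrast, so these counts say nothing about chance. For the difference between the lines the real grouping called 0 genes for SY200, V50 and SY200/V50, so that 40 of 40 splits had to give as many, which says nothing about chance. The highest other splits gave 2, 2 and 881, in edgeR, and the real grouping had 1048, 1873 and 3009 genes at an unadjusted p under 0.05 and 33, 120 and 421 with DESeq2.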

How the results depend on the processing

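The swaps of labels and the test with separate controls were chosen after seeing the results, unlike the alternatives below. No paired analysis was possible by replicate number because the labels give none shared between conditions, and libraries were matched by cell line and time instead. Where leaving out a library leaves 1 in an arm, that sample is assumed to vary like the other groups. The scaling, the cell line block, the filter on low counts, the tool and single libraries each moved counts by more than 1.5 times.

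Without the filter on low counts edgeR called 227 genes for SY200, 529 for the departure from the sum, 123 for SY200 at 12 h against 3 h, 1598 and 1410 for the difference of that change between SY200/V50 and SY200 or V50. It called 1 for the SY200/V50 effect between the lines, and 50 for DMSO against parental. For the knockouts it called 1742 for CDK1 KO, 996 for CDK7 KO, 2782 for CDK9 KO, 3212 for CDK7/9 KO, 1426 for CDK7/9 KO against CDK7 KO and 18 against CDK9 KO. DESeq2 called 986 for SY200, 1915 for the departure from the sum, 1383 for SY200 at 12 h against 3 h, and 4191 for the difference from V50. It called 33, 120 and 421 for the SY200, V50 and SY200/V50 effects between the lines, and 122 for DMSO against parental. For the knockouts DESeq2 called 412 for CDK1 KO, 199 for CDK7 KO and 4 for CDK7/9 KO against CDK9 KO.

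With mitochondrial scaling the counts were 5299 for SY200, 14273 for V50, 15832 for SY200/V50, and 13645 and 6607 for SY200/V50 against SY200 and V50. They were 208 and 10596 for 12 h against 3 h of SY200 and SY200/V50, 7491 and 4922 for the differences of this change from SY200 and V50, 12 and 36 for the SY200 and SY200/V50 effects between the lines, and 2 for DMSO against parental. For the knockouts they were 0 for CDK1 KO (412 with DESeq2), 1 for CDK7 KO, 11411 for CDK9 KO, 11138 for CDK7/9 KO, and 1789 and 0 for CDK7/9 KO against CDK7 KO and CDK9 KO. The share of called genes that were higher went from 48.8% to 3.81% for SY200, 46.7% to 2.16% for V50, and 49.7% to 1.08% for SY200/V50. It went from 50.3% to 87.5% for SY200 at 12 h against 3 h, 62.2% to 47.9% for V50 and 52.3% to 1.47% for SY200/V50. With DMSO alone as the control 44 genes were called for SY200, 212 for the departure from the sum and 606 for SY200 at 12 h against 3 h.

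Without the cell line block the counts were 0 for SY200, 103 for V50, 2364 for SY200/V50, and 2062 and 252 for SY200/V50 against SY200 and V50. They were 0 for the departure from the sum, 0, 0 and 33 for 12 h against 3 h of SY200, V50 and SY200/V50, 0 for both differences of this change and 0 for DMSO against parental. Without the time block 2 genes were called for CDK7/9 KO against CDK9 KO. Of 198 list tests, in the 3 treatments against control, the combination against each agent and the 4 knockouts against empty vector, 102 were called with the preset correlation and 3 with an estimated correlation. With genes of at least 10 CPM the correlation of SY200/V50 with CDK7/9 KO was 0.0303. For SY200, V50 and SY200/V50 it was 0.138, -0.0692 and 0.0209 with CDK7 KO, and 0.126, -0.163 and -0.101 with CDK1 KO. DESeq2's size factors moved no main comparison's total count by more than 1.5 times.

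Under mitochondrial scaling genes that turned with V50 were FOXM1 (-0.27), TYMS (-0.26), RPS20 (-0.29), RPSA (-0.31), MT-CO2 (-0.05) and COX7C (-0.33). With SY200/V50 it turned BIRC5 (-0.89), RPSA (-0.43), RPS20 (-0.55), MT-CO2 (-0.04), NDUFA4 (-0.56), COX7C (-0.54), FOXM1 (-0.68) and FANCI (-0.69), and in CDK9 KO CCNT1 (-0.37). COL6A1, SY200/V50 against V50, turned to -0.08 and -0.24 without the MDA-MD-231 SY200/V50 3 h and 6 h library and rose to 1.57 without the MDA-MD-231 V50 6 h library. List medians turned under mitochondrial scaling for cytosolic ribosomal protein and nuclear oxidative phosphorylation genes with SY200 (-0.30 and -0.24), V50 (-0.39 and -0.51), SY200/V50 (-0.67 and -0.73), SY200/V50 against SY200 (-0.37 and -0.47) and against V50 (-0.28 and -0.21). They also turned for DNA replication and E2F genes with V50 (-0.62), hypoxia and glycolysis genes in SY200/V50 against V50 (-0.17), and p53 target (-0.22), interferon-stimulated (-0.07) and oncogenic transcription factor and receptor genes (-0.18) in CDK1 KO. In the other knockouts it turned cholesterol synthesis (-0.20), oncogenic transcription factor and receptor (-0.22) and YAP and TEAD target genes (-0.11) in CDK7 KO, histone (-0.27) and zinc finger genes (-0.68) in CDK9 KO, and zinc finger genes in CDK7/9 KO (-0.67). With DESeq2's size factors the median of DNA replication and E2F genes in SY200/V50 against V50 turned to 0.01.

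Over all libraries left out in turn the counts ranged from 59 to 624 for SY200, 2628 to 4917 for V50, 7759 to 9206 for SY200/V50, 7171 to 8812 and 1637 to 5020 for SY200/V50 against SY200 and V50, and 286 to 2667 for the departure from the sum. They ranged from 0 to 757, 226 to 3057 and 1020 to 3628 for 12 h against 3 h of SY200, V50 and SY200/V50, 705 to 3857 and 525 to 3816 for the differences of this change from SY200 and V50. The ranges were 0 to 4, 0 to 2 and 0 to 278 for the SY200, V50 and SY200/V50 effects between the lines, and 0 to 29 for DMSO against parental. For the knockouts the ranges were 0 to 6976 for CDK1 KO, 1 to 6239 for CDK7 KO, 0 to 6984 for CDK9 KO, 0 to 7329 for CDK7/9 KO, and 0 to 4135 and 0 to 76 for CDK7/9 KO against CDK7 KO and CDK9 KO.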

Other observations

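The test with separate controls was chosen only after the result it measures was seen.

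With SY200/V50 at 3 h the lists that passed camera with either correlation were led by immediate-early genes (16 of 28 lower, 20 adjusted over the list alone, camera adjusted p = 4.71e-16, adjusted p = 0.0382 with an estimated correlation) and p53 targets (10 of 24 lower, also adjusted over the list alone, camera adjusted p = 1.52e-06, adjusted p = 0.0205 with an estimated correlation). The others were pro-apoptotic genes (2 of 20 lower, 4 adjusted over the list alone, camera adjusted p = 0.0076, adjusted p = 0.0401 with an estimated correlation), zinc finger genes (200 of 495 lower, 298 lower and 2 higher adjusted over the list alone, camera adjusted p = 1.19e-42, adjusted p = 0.0401 with an estimated correlation) and mitochondrially encoded mRNAs (13 of 13 higher, also adjusted over the list alone, camera adjusted p = 6.92e-17, adjusted p = 0.0382 with an estimated correlation). The mitochondrial mRNAs, which another polymerase makes, were thus higher on the TMM scale, and the other lists had no member higher over all genes. Without the MDA-MD-231 or MDA-MD-468 SY200/V50 3 h library 181 and 169 genes were called at 3 h, against 1426. Against SY200 at 3 h immediate-early genes (2 of 28 lower, 20 adjusted over the list alone, camera adjusted p = 3.61e-30, adjusted p = 0.0122 with an estimated correlation) and p53 targets (0 of 24 past the threshold, 3 lower adjusted over the list alone, camera adjusted p = 1.55e-05, adjusted p = 0.0208 with an estimated correlation) were lower with the combination. The 20 most abundant genes took 7.21% of counts with DMSO and 12.2% after 12 h of SY200/V50 in MDA-MD-231, and 8.71% and 20.7% in MDA-MD-468.

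The first pattern was that 4532 genes were higher with SY200/V50 than in the control while RNA polymerase II kinases were the named targets. A fall of most other mRNAs may lift the rest on a relative scale. Under mitochondrial scaling 3.77% of these genes (171) stayed higher and 3171 turned lower, which is what this explanation needs. This scaling moves all genes alike, so the result reflects the mitochondrial share alone and would come out the same if mitochondrial mRNAs themselves rose. Their amount per cell was not measured, and the parental MDA-MD-231 libraries of the inhibitor and knockout parts already differed, with 2.17% and 5.05%. At matched 3' UTR length 42.2% of the genes that rose and 51.3% of those that fell had at least 3 AUUUA motifs, a difference of -9.12 points (interval -11 to -7.3). Among genes with an annotated 3' UTR, those that rose thus held fewer motifs. Whether this accounts for the rises stays open, since the interval spans the 10 points set beforehand and 73.6% of the higher genes have an annotated 3' UTR. No external standard or cell count is given, so whether these genes rose in absolute amount stays open.

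The second pattern was the return of genes lower with V50 at 3 h towards the control at 12 h, which SY200/V50 lacked. It was not from 1 line alone, as the lower of the lines' medians at 12 h with V50 was -0.0112, against -1.9 and -2.71 with SY200/V50. With separate controls 83.1% and 94.9% of genes were lower at 12 h with SY200/V50, so shared controls did not keep them low. The gap to V50 (75.8 and 85.1 points) used 1 control for both and cannot test the return. These genes were shorter than others at matched expression (median length ratio 0.552, interval 0.493 to 0.601), so gene length may contribute. No biological explanation or effect of time alone was tested.

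The third pattern was that CDK7 KO called 4 genes although CDK7 mRNA fell in both of its libraries. An empty vector library out of place may explain this, as 235 genes were called without the 96 h empty vector library, and 6239 without the 72 h one. By root mean square log2 distance the 96 h library lay 0.405 to 0.476 from the 8 knockout libraries, whereas the 72 h one lay 0.172 to 0.291 from them, so the 96 h library was the one that stood apart. Why it did was not tested. An incomplete loss of CDK7 in the cells, with 20.5% to 31% of its mRNA left, stays open and was not tested.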
